A study of Homo sapiens and Mus musculus with 24 samples.

How the data were processed

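The series covered a human and a mouse system. EndoC-βH1 cells, an established human pancreatic beta-cell line, were transfected with a control siRNA (siControl) or with an siRNA against METTL3 or METTL14, the catalytic and the RNA-binding subunit of the m6A methyltransferase complex, with 3 replicates per group. For each replicate an m6A immunoprecipitation library (IP) and an input library were sequenced, a procedure called m6A-seq. The mouse libraries came from sorted beta cells of wild-type animals (n = 3) and of animals with a knockout of Mettl14 restricted to beta cells (n = 3). Per the labels, RNA was selected on oligo-dT beads and depleted of ribosomal RNA. The design text and the sample protocols name different library kits for the m6A libraries, and which was used is not given in the sources used here. The submitters' processing notes name TopHat2, featureCounts and DESeq2 version 1.18.1 without a role for each, and the build hg38, also for the mouse samples. The mouse build, the annotation, the strand setting of the counting and the peak caller are not given in the sources used here.

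The deposited mouse gene table held raw read counts over 24421 genes, with 6992020 to 8345539 reads per library. The deposited tables of IP and input reads per peak also held raw counts, over 10591 peaks for the METTL3 knockdown and 11547 for the METTL14 knockdown. For each of the 5115 peaks with the same position and blocks in both lists, the control counts were identical between them. The authors deposited a log2 ratio for each peak, which was recomputed as the log2 of knockdown over control of the ratio of IP to input, from group means of each library's share of its total over the peaks. The deposited and the recomputed values differed by no more than 8e-15, and 145 and 143 peaks had no finite value, of which 145 and 142 had an input mean of 0 in a group. The authors also deposited a p value and a false discovery rate (FDR) per peak from a test whose tool is not given in the sources used here. Input tables held 2116924 to 2624217 reads in peaks per library, and IP libraries had 7798310 to 8866734. The human gene tables deposited by the authors, over 24116 genes, held a normalized score, input read counts divided by a size factor per library and rounded to whole numbers. This was read from the values. The same control libraries differed between both gene tables by constant factors of 1.01, 1.02 and 1.02, and siControl replicate 1 lacked 12 and 14 of the whole numbers under 200 in the METTL3 and the METTL14 table. The median ratio to the geometric mean over libraries spanned 0.0011 and 0.0009 in the human gene tables, against 0.179 in the mouse table.

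The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, with the exceptions stated here and in the closing section. The human gene tables had been assumed to hold raw counts for edgeR. Since they held normalized values, expression in the knockdowns was tested with limma instead (version 3.58.1, trended empirical Bayes variances) on log2 of the value plus 1, for genes with a value of at least 10 in at least 3 libraries. Expression in the mouse was tested with edgeR (version 4.0.16) by its quasi-likelihood F test, TMM factors and filterByExpr. Peaks were tested with edgeR in 1 model over IP and input counts, where the interaction of knockdown and assay is the change of IP relative to input, with TMM factors within each assay and filterByExpr over the IP columns. All p-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, and genes or peaks with an adjusted p under 0.05 were called. A direct expression test of METTL14 against METTL3 knockdown had been made conditional on identical control values. It was not run, since the tables were normalized separately, and both knockdowns were compared on the peaks they share instead. R was version 4.3.3.

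Fixed gene lists were tested with camera (limma), with a preset inter-gene correlation of 0.01, when at least 5 members were tested. This gave 22 lists for the METTL3 knockdown, 23 for the METTL14 knockdown and 25 for the mouse, and p-values were adjusted over the lists of a comparison. Counts of called members were also made with p-values adjusted over the list alone. No list call held with a correlation estimated from the libraries, and those p-values stand beside the calls. The genes named were METTL3 and METTL14, the 8 called genes with the largest change in each direction with a mean log2 CPM (counts scaled to a common library total) of at least 4 and no overlap of the groups (symbols of predicted genes and of common non-coding classes left out), the 3 members with the smallest p of each called list, and INS, PDX1, MAFA, IGF1R and AKT1. Peaks named were those called and the peak with the most IP reads in each of PDX1, INS, MAFA, IGF1R, AKT1, IRS2, SLC2A2 and NKX6-1, where one was listed. Some genes that the rule names are not reported. Other genes are said to have been chosen after their values were seen.

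Values per gene are means with standard deviation (SD) over 3 libraries, in normalized counts for the human cells and in TMM-scaled CPM for the mouse unless stated. Fold changes are log2 values with the standard error (SE) of the model. The labels do not say whether replicates of the cell line were separate cultures or whether each mouse library was 1 animal, so p-values measure the spread between these libraries. Replicate numbers were not taken as pairs. Replicate libraries of the mouse and of the IP tables were checked in pairs for duplicates, and the chi-square per degree of freedom of 9.43 to 44.3 showed none.

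Fold changes were correlated across genes between both knockdowns, with 100 simulated pairs of unchanged groups set against the same controls, and between each knockdown and the mouse knockout over genes of the same symbol. Genes with a deposited peak were compared with the other genes by camera. On simulated counts, changes were planted only in genes above the median count. The expression tests called 86, 89 and 27 of 100 genes changed 2-fold and 100, 100 and 88 of 100 changed 4-fold (METTL3 knockdown, METTL14 knockdown, mouse), with 4, 10 and 8 false calls. Peak changes were planted only in peaks with input counts above the median, and none under 4-fold was planted. The interaction test called 73 and 74 of 100 peaks with a 4-fold and 91 and 89 of 100 with an 8-fold change of IP relative to input (METTL3 and METTL14 knockdown), with 17 and 15 false calls. It called 0 of 200 peaks whose transcript alone changed 4-fold, whereas the test on IP counts alone called all 200.

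Alternatives were DESeq2 (version 1.42.0), edgeR with median-of-ratios size factors, no filter on low values, column totals in place of TMM, IP counts alone, limma on the difference of log2 IP and log2 input, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were the edgeR test first intended, run on the rounded values, the direct test of both knockdowns on shared peaks, pseudocounts of 0.5 and 5, the input value of the gene in place of that of the peak, a tie of IP and input within a sample, and the left-out libraries for the lists, correlations and genes with a peak. No spike-in was described, and IP counts were scaled to the reads within peaks, so a change of m6A common to all peaks was not measurable and was not analysed here.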

Results

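EndoC-βH1 cells were profiled by m6A-seq after transfection with siControl, siMETTL3 or siMETTL14 (n = 3 per group, an IP and an input library each), and sorted mouse beta cells by RNA-seq (n = 3 wild type, n = 3 knockout), which gave 24 libraries. The normalized human gene tables summed to between 10419649 and 10976768 per library. The peak tables held 7798310 to 8866734 IP reads and 2116924 to 2624217 input reads per library, and the mouse libraries held 6992020 to 8345539 reads.

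METTL3 fell after its knockdown and METTL14 was not called lower after its own. Normalized METTL3 counts were 441, 227 and 293 in the controls and 26, 142 and 88 after siMETTL3, a log2 fold change of -2.14 (SE 0.44, adjusted p = 0.00398, limma). The call was lost without siControl replicate 1 (adjusted p = 0.0662). METTL14 counts in the same libraries were 228, 290 and 175 against 469, 275 and 557, with a log2 fold change of 0.88 (SE 0.27, adjusted p = 0.0578). It was called by DESeq2 and by edgeR with median-of-ratios size factors, and with a library left out the adjusted p ran from 0.00277 (log2 fold change 1.17 without siMETTL3 replicate 2) to 0.285 (without siMETTL3 replicate 3). After siMETTL14 the METTL14 counts were 132, 48 and 174, against 232, 295 and 178 in the controls (log2 fold change -1.15, SE 0.37, adjusted p = 0.0749). The library labelled siMETTL14 replicate 3 was close to the lowest control, and without it the log2 fold change was -1.52 (adjusted p = 0.0425), whereas without siMETTL14 replicate 2 it was -0.60 (adjusted p = 0.313). METTL3 had a log2 fold change of -0.01 (SE 0.27) after siMETTL14. In the mouse, Mettl14 reads numbered 122, 191 and 59 in wild type and 154, 99 and 86 in the libraries labelled knockout, with a log2 fold change of -0.01 (SE 0.74, adjusted p = 0.999, edgeR quasi-likelihood). Reads over the whole gene may lie outside the deleted part, whose position is not given in the sources used here. Mettl3 had a log2 fold change of -0.58 (SE 0.41, adjusted p = 0.665) in the mouse.

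**Figure D1:**
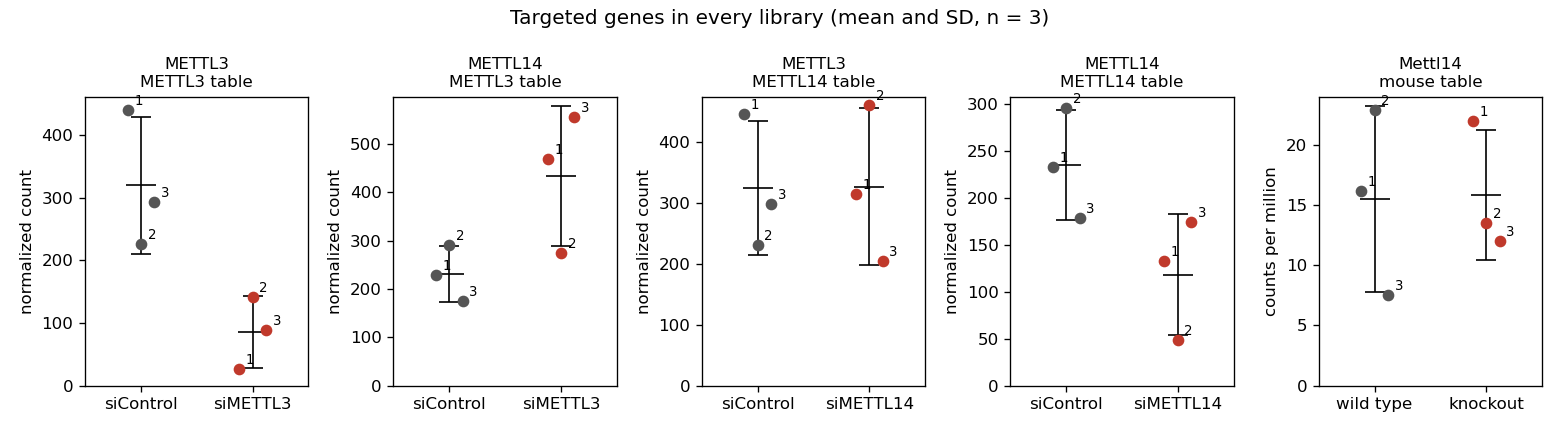
METTL3 and METTL14 in every library, as normalized counts for EndoC-βH1 cells and counts scaled to the library total for mouse beta cells. Each point is 1 library, grouped by siRNA or genotype.

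The METTL3 knockdown was compared with siControl to ask which transcripts depend on the catalytic subunit. TBX2, a developmental transcription factor, rose from a mean normalized count of 28.0 ± 24.4 to 320 ± 32.9 (SD, n = 3), a log2 fold change of 3.79 (SE 0.49). CBLN2, a synaptic organizer, rose from 80.3 ± 20.03 to 777 ± 29.2 (log2 fold change 3.29, SE 0.26), and the neuropeptide gene NPY from 52.0 ± 21.1 to 457 ± 73.2 (3.19, SE 0.35). The nuclear receptor gene ESRRG (2.26, SE 0.34), the BMP-binding CRIM1 (2.21, SE 0.32), the receptor gene ROR1 (2.03, SE 0.24), the COPII coat gene SEC23A (1.66, SE 0.28) and the transcriptional adaptor LMO2 (1.65, SE 0.21) also rose. RAMP1, which encodes a subunit of the CGRP receptor, fell from 410 ± 110 to 59.7 ± 19.7 (-2.78, SE 0.35). The corepressor gene TLE3 fell from 531 ± 48.6 to 84.7 ± 13.9 (-2.64, SE 0.27). The receptor kinase gene RET (-2.45, SE 0.32), the ETS factor gene ETV4 (-2.41, SE 0.42), IGFALS, whose product binds IGF complexes (-1.96, SE 0.31), the natriuretic peptide receptor gene NPR1 (-1.96, SE 0.37) and the matrix gene VTN (-1.89, SE 0.30) fell. Each of these 15 genes stayed called with any 1 library left out.

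Of 14059 genes tested, 839 were called, 402 higher and 437 lower. Before adjustment 2774 genes had p under 0.05. The number called depended on single libraries. It was 371 without siControl replicate 1, 288 without siControl replicate 3, 341 without siMETTL3 replicate 1, 1925 without siMETTL3 replicate 2 and 431 without siMETTL3 replicate 3.

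Among beta-cell transcription factors, 5 of 21 rose and 2 fell, and 6 rose and 3 fell when adjusted over the list alone. NEUROD1, RFX6, BACH2 (3.11), FOXA1 (1.04) and MAFA rose, and NKX6-1 and HNF4A (-0.50) fell. NEUROD1, needed for insulin transcription, rose from 2952 ± 102 to 6808 ± 1284 (1.19, SE 0.13), whereas NKX6-1, which maintains beta-cell identity, fell from 1491 ± 263 to 552 ± 166 (-1.46, SE 0.19). RFX6 rose by 0.83 (SE 0.12). These genes except MAFA were chosen after their values were seen. MAFA, an activator of the insulin promoter, had a log2 fold change of 0.39 (SE 0.12, adjusted p = 0.0498), and the call was kept in 1 of 6 fits with a library left out, with an adjusted p of up to 0.219 without siControl replicate 2. The list as a whole was not called (camera adjusted p = 0.350).

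Of 28 genes of insulin production and glucose sensing, 5 rose and none fell, and 6 rose and 1 fell when adjusted over the list alone. The zinc transporter gene SLC30A8, which loads insulin granules with zinc, rose from 3714 ± 610 to 9148 ± 1097 (1.31, SE 0.12). The prohormone-processing genes PCSK1 (0.71, SE 0.11) and CPE (0.48, SE 0.09), the oxidoreductase gene ERO1B (0.96, SE 0.15) and the phosphatase gene G6PC2 (0.93, SE 0.19) rose too, and all 5 were chosen after their values were seen. INS had a log2 fold change of -0.27 (SE 0.11, adjusted p = 0.178) and PDX1 of -0.24 (SE 0.10, adjusted p = 0.188). Without siMETTL3 replicate 2 INS was called at -0.42 (adjusted p = 0.000862), and without siControl replicate 3 its adjusted p was 0.631. The camera adjusted p of the list was 0.0684, and 0.0223 without siControl replicate 3. In insulin and IGF1 signalling, AKT1 fell from 5053 ± 267 to 3582 ± 156 (-0.50, SE 0.11, adjusted p = 0.00687). The AKT1 call was lost without siControl replicate 1 (adjusted p = 0.0686), siControl replicate 3 (0.0554) or siMETTL3 replicate 1 (0.0711). IGF1R had a log2 fold change of -0.28 (SE 0.14, adjusted p = 0.245).

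Genes of the unfolded protein response were higher as a list and those of cytoplasmic ribosomal proteins lower. In the unfolded protein response, 6 of 28 genes rose and none fell, with the same counts when adjusted over the list alone (median log2 fold change 0.22, camera adjusted p = 0.00951, adjusted p = 0.640 with an estimated correlation, 0.0744 without siMETTL3 replicate 2). MANF, a secreted survival factor, rose by 0.75 (SE 0.15). The chaperone gene HSP90B1 rose by 0.53 (SE 0.13) and the sensor gene ERN1 by 1.27 (SE 0.31). HSP90B1 lost its call without siControl replicate 1 (adjusted p = 0.0574), siControl replicate 3 (0.160), siMETTL3 replicate 1 (0.108) or siMETTL3 replicate 3 (0.106), and ERN1 without siControl replicate 3 (0.108) or siMETTL3 replicate 1 (0.0522). Of 81 ribosomal protein genes 10 fell and none rose, and 21 fell when adjusted over the list alone (median -0.26, camera adjusted p = 4.82e-09, adjusted p = 0.640 with an estimated correlation). RPS2 (-0.51, SE 0.11), RPL35 (-0.54, SE 0.13) and RPL31 (-0.56, SE 0.13) fell. RPS2 kept its call in 3 of 6 fits with a library left out, with an adjusted p of up to 0.0779 without siMETTL3 replicate 1. RPL35 kept its call in 2 of 6 (up to 0.115 without siControl replicate 1) and RPL31 in 2 of 6 (up to 0.0844 without siMETTL3 replicate 1).

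The METTL14 knockdown was compared with the same controls to ask which transcripts depend on the RNA-binding subunit. The metallothionein gene MT2A, which binds zinc and copper, rose from 81.0 ± 32.4 to 279 ± 48.7 (SD, n = 3), a log2 fold change of 1.83 (SE 0.33), and MT1X rose by 1.45 (SE 0.29). ZNF268 (1.79, SE 0.30), the endosomal WDFY1 (1.56, SE 0.21), KLHL24, a ubiquitin ligase adaptor (1.41, SE 0.26), the growth factor gene MDK (1.37, SE 0.19), the calcium channel gene TMCO1 (1.32, SE 0.17) and the palmitoyltransferase gene ZDHHC17 (1.27, SE 0.29) rose. TLE3 fell from 539 ± 48.1 to 142 ± 21.9 (-1.93, SE 0.24), and RAMP1 (-1.45, SE 0.27), ETV4 (-1.46, SE 0.33) and TMEM87A (-1.22, SE 0.20) fell. PCP4 (-1.27, SE 0.30), TM4SF4 (-1.16, SE 0.31), CFC1B (-1.15, SE 0.26) and SUSD4 (-1.14, SE 0.28) fell as well. Calls were lost for MT1X without siMETTL14 replicate 2 (adjusted p = 0.0528), for PCP4 without siControl replicate 1 (0.0827), for ZDHHC17 without siControl replicate 1 (0.0553) or siMETTL14 replicate 3 (0.0568), for CFC1B without siControl replicate 1 (0.0609) or 3 (0.0513) and for SUSD4 without siControl replicate 3 (0.160) or siMETTL14 replicate 3 (0.0561). ETV4 kept its call in 3 of 6 such fits (up to 0.0963 without siControl replicate 3) and TM4SF4 in 2 of 6 (up to 0.174 without siControl replicate 3).

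Of 14143 genes tested, 586 were called, 360 higher and 226 lower, and 338 were called without a filter on low values. Before adjustment 2657 genes had p under 0.05. The number called was 227 without siControl replicate 1, 231 without siControl replicate 3, 360 without siMETTL14 replicate 1 and 207 without siMETTL14 replicate 3.

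Genes chosen after their values were seen moved as in the METTL3 knockdown. NEUROD1 rose by 0.62 (SE 0.11), RFX6 by 0.54 (SE 0.11) and SLC30A8 by 0.59 (SE 0.11), and NKX6-1 fell by 0.78 (SE 0.15). INS had a log2 fold change of -0.12 (SE 0.08, adjusted p = 0.467), PDX1 of -0.31 (SE 0.10, adjusted p = 0.0884), MAFA of 0.12 (SE 0.11), IGF1R of 0.08 (SE 0.12) and AKT1 of 0.08 (SE 0.10), none of them called by limma over all libraries. PDX1 was called without siMETTL14 replicate 1 (-0.43, adjusted p = 0.0329), and its adjusted p was 0.268 without siMETTL14 replicate 2. Of 21 beta-cell transcription factors 2 rose and 1 fell, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.474). Of 28 genes of insulin production and glucose sensing 2 rose and none fell, and 4 rose when adjusted over the list alone (camera adjusted p = 0.294).

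Ribosomal protein, OXPHOS, glycolysis and cholesterol genes were lower as lists. In the same libraries the nuclear RNA MALAT1, chosen after its values were seen, rose by 0.50 (SE 0.11, adjusted p = 0.00842, limma). MALAT1 was not among the genes called in both knockdowns. Of 81 ribosomal protein genes 26 fell and none rose, and 61 fell when adjusted over the list alone (median log2 fold change -0.37, camera adjusted p = 9.12e-19, adjusted p = 0.333 with an estimated correlation). RPL27 (-0.59, SE 0.11) and RPL6 (-0.57, SE 0.12) fell. Of 79 nuclear genes of oxidative phosphorylation (OXPHOS) 11 fell and none rose, and 20 fell when adjusted over the list alone (median -0.28, camera adjusted p = 7.52e-09, adjusted p = 0.333 with an estimated correlation). The complex I gene NDUFS6 (-0.72, SE 0.14), the complex III gene UQCRFS1 (-0.66, SE 0.14) and the complex IV gene COX7C (-0.55, SE 0.12) fell. The UQCRFS1 and COX7C calls were lost without siControl replicate 1 (adjusted p = 0.0569 and 0.0662).

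Of 18 glycolysis genes 4 fell and none rose, and 9 fell when adjusted over the list alone (median -0.30, camera adjusted p = 0.00193, adjusted p = 0.404 with an estimated correlation). ENO1 (-0.58, SE 0.10), LDHA (-0.58, SE 0.12) and PKM (-0.44, SE 0.10) fell, the last not called without siControl replicate 1 (adjusted p = 0.0966). Of 25 cholesterol synthesis genes 6 fell and none rose, and 10 fell when adjusted over the list alone (median -0.25, camera adjusted p = 0.00321, adjusted p = 0.333 with an estimated correlation). ACAT2 (-0.63, SE 0.11) and FDFT1 (-0.43, SE 0.09) fell. In the METTL3 knockdown the glycolysis list (5 of 18 lower, median -0.25) was not called by camera (adjusted p = 0.0728). Neither were the OXPHOS list (1 of 79 lower, median -0.12, 0.0577) and the cholesterol list (1 of 25 lower, median -0.09, 0.233). No member of these lists was called higher there, and ENO1, LDHA and PKM were called lower in both knockdowns.

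Of 35 proteasome subunit genes 2 fell and none rose, and 3 fell when adjusted over the list alone (median -0.15, camera adjusted p = 0.00614, adjusted p = 0.333 with an estimated correlation, 0.0510 without siControl replicate 1). PSMB5 (-0.58, SE 0.13) and PSMA7 (-0.41, SE 0.11) fell, whereas PSMB1 had -0.41 (SE 0.13, adjusted p = 0.0701, called by DESeq2 alone among the other tools). PSMB5 lost its call without siControl replicate 1 (adjusted p = 0.110) or siMETTL14 replicate 3 (0.0656), and PSMA7 kept its call in 2 of 6 fits with a library left out (up to 0.209 without siControl replicate 3). Of 42 genes of the cell cycle 2 rose and 3 fell, and 2 rose and 7 fell when adjusted over the list alone (median -0.17, camera adjusted p = 0.0280, adjusted p = 0.333 with an estimated correlation). The list call was lost without siControl replicate 1 (0.128), siControl replicate 3 (0.0506) or siMETTL14 replicate 2 (0.129). RRM2, which makes deoxynucleotides, fell by 0.64 (SE 0.10), and the kinase genes CDK2 and CDK1 rose by 0.67 (SE 0.16) and 0.71 (SE 0.17). Each kinase gene kept its call in 3 of 6 such fits (adjusted p of up to 0.0981 for CDK2 without siControl replicate 1 and 0.0919 for CDK1 without siControl replicate 3).

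**Figure D2:**
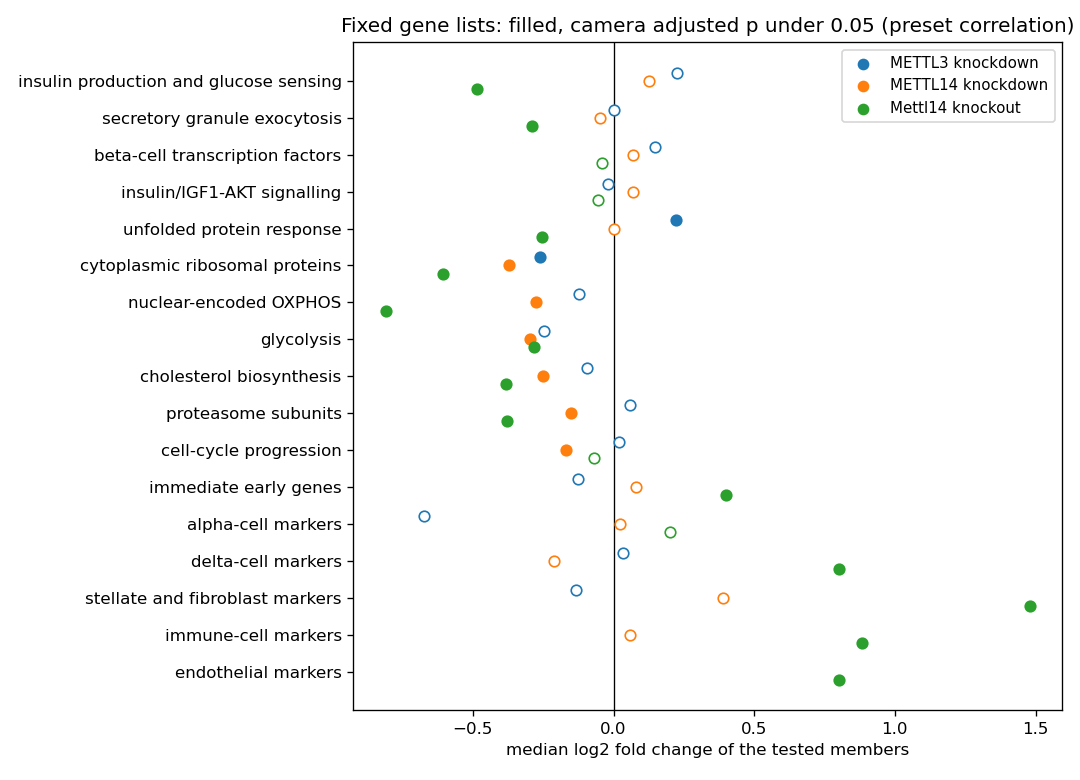
Median log2 fold change of the fixed gene lists in the METTL3 knockdown, the METTL14 knockdown and the Mettl14 knockout. Colours mark comparisons, and filled points have a camera adjusted p under 0.05 with the preset correlation.

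Changes in both knockdowns were compared to ask whether loss of either subunit acted on the same transcripts. TLE3, RAMP1, ETV4 and NKX6-1 were lower, and SLC30A8, NEUROD1 and RFX6 higher, in both. Over 13841 genes the log2 fold changes had a Spearman correlation of 0.56. The controls were shared, and simulated unchanged groups set against 1 set of controls gave a mean of 0.450. The Pearson correlation was 0.562, against a simulated mean of 0.502 and a highest simulated value of 0.538. The covariance was 0.188, against a mean of 0.106 and a highest value of 0.119 in 100 simulations. Called in both knockdowns were 218 genes, 148 higher in both (10.3 for independent lists) and 66 lower in both (7.14 for independent lists). ABLIM1, FGFR3, MFAP4 and RTN4RL1 were called in opposite directions. In the simulations no gene was called in both. The simulations drew each gene independently, so they lack the correlation between genes within a library. Their highest values and those for independent lists therefore do not bound what shared controls can give. Because 3 controls cannot be divided between the comparisons, part of the overlap may come from the shared controls.

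**Figure D3:**
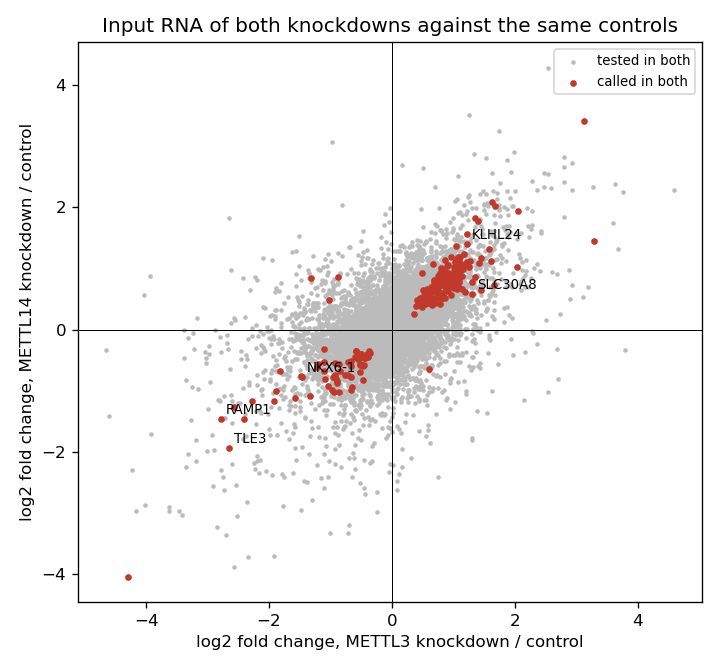
Log2 fold change of each gene in the METTL3 knockdown on the horizontal axis and in the METTL14 knockdown on the vertical axis. Genes called in both are coloured.

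The mouse libraries labelled knockout, in which Mettl14 reads were not lower, were compared with wild type to ask how the labelled deletion changed beta cells. Ins2 fell from 12350 ± 648 to 1654 ± 146 CPM (SD, n = 3), a log2 fold change of -2.90 (SE 0.06). Ins1 fell from 3668 ± 161 to 355 ± 43.5 (-3.37, SE 0.10) and Iapp, which encodes amylin, from 9482 ± 632 to 2932 ± 359 (-1.69, SE 0.07). Mafa, an activator of insulin transcription, fell from 199 ± 24.8 to 13.6 ± 7.0 (-3.87, SE 0.34). The protease gene Prss53 (-4.11, SE 0.19), Fam151a (-5.58, SE 0.48), the metallothionein gene Mt1 (-3.66, SE 0.28) and Msln (-3.47, SE 0.43) fell. Igf1r, the receptor of IGF1, fell from 913 ± 82.9 to 283 ± 31.1 (-1.69, SE 0.13). Col20a1, a collagen gene, rose from 12.4 ± 3.97 to 194 ± 21.2 (3.96, SE 0.30). Each of these 10 genes stayed called with any 1 library left out.

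Other calls were lost in fits with a library left out. Akt1 fell by 0.74 (SE 0.18, adjusted p = 0.0397) and was called in 0 of 6 such fits, with a log2 fold change of -0.82 to -0.68 and an adjusted p of up to 0.171 without wild-type replicate 3. Fn1 rose by 4.53 (SE 0.86, 4.07 to 6.05 with a library left out), not called without knockout replicate 1 (adjusted p = 0.0707) or 2 (0.0501). Nbl1 rose by 3.25 (SE 0.61, 3.13 to 3.44 with a library left out), not called without knockout replicate 1 (0.0575) or 3 (0.0647), and Galr1 by 2.47 (SE 0.48, 2.17 to 3.16), not called without wild-type replicate 3 (0.0515) or knockout replicate 3 (0.0526). Alk fell by 3.62 (SE 0.66), not called without wild-type replicate 2 (0.0542) or 3 (0.120). Mt2 (-3.72, SE 0.77) and Sema4g (2.71, SE 0.56) kept the call in 2 of 6 fits, with an adjusted p of up to 0.0789 without knockout replicate 2 and 0.0843 without knockout replicate 1. Mlph (-4.33, SE 1.06), Prss23 (2.72, SE 0.59), Gpr146 (2.61, SE 0.60) and Tmem255a (2.45, SE 0.55) kept it in 1 of 6, with adjusted p-values of up to 0.255 without wild-type replicate 3, 0.130 without knockout replicate 2, 0.136 without knockout replicate 3 and 0.251 without knockout replicate 1. Their log2 fold changes in these fits were -7.41 to -3.79, 2.33 to 3.43, 2.27 to 3.51 and 1.94 to 2.76. Pdx1 had a log2 fold change of -0.35 (SE 0.36, adjusted p = 0.827).

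Of 12527 genes tested, 307 were called, 123 higher and 184 lower. DESeq2 called 1046 (515 higher, 531 lower), and edgeR without a filter on low values 549 (217 higher, 332 lower). Before adjustment 1615 genes had p under 0.05. The number called was 181, 143 and 164 without wild-type replicate 1, 2 and 3, and 179, 149 and 167 without knockout replicate 1, 2 and 3.

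Genes of insulin production and glucose sensing fell as a list, and markers of some other cell types were higher in the same libraries. Of 28 insulin genes 13 fell and none rose, and 2 rose and 19 fell when adjusted over the list alone (median log2 fold change -0.49, camera adjusted p = 5.55e-10, adjusted p = 0.0553 with an estimated correlation). G6pc2 (-2.46, SE 0.19), the GABA-synthesis gene Gad1 (-3.19, SE 0.57) and the incretin receptor gene Glp1r (-0.96, SE 0.16), chosen after their values were seen, fell and kept their calls with any library left out. Of 34 genes of granule exocytosis 4 fell and none rose, and 10 fell when adjusted over the list alone (median -0.29, camera adjusted p = 0.00264, adjusted p = 0.0825 with an estimated correlation). The granule effector gene Sytl4 (-2.22, SE 0.18), Chga (-0.38, SE 0.06) and Rab27a (-0.86, SE 0.18) fell. Rab27a was not called without wild-type replicate 1 (adjusted p = 0.0593), wild-type replicate 2 (0.0891) or knockout replicate 1 (0.0580). In the same libraries the median log2 fold change was 0.88 for immune-cell, 1.48 for stellate and fibroblast, and 0.80 for both delta-cell and endothelial markers.

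Markers of immune, delta, stellate and endothelial cells were higher as lists, and those of alpha, PP, ductal and acinar cells were not called. Of 20 immune-cell markers 2 rose, and 2 when adjusted over the list alone (camera adjusted p = 1.54e-06, adjusted p = 0.0611 with an estimated correlation), with Laptm5 at 2.39 (SE 0.38), the macrophage lysozyme gene Lyz2 at 0.93 (SE 0.17) and Csf1r, called by DESeq2 and not by edgeR, at 0.89 (SE 0.31). Of 9 delta-cell markers 3 rose, and 6 when adjusted over the list alone (camera adjusted p = 3.03e-05, adjusted p = 0.0774 with an estimated correlation). Frzb rose by 0.75 (SE 0.16) and Ptprz1 by 1.69 (SE 0.37), each kept in 1 of 6 fits with a library left out, with adjusted p-values of up to 0.106 and 0.123 without knockout replicate 2. Of 13 stellate and fibroblast markers 1 rose, and 3 when adjusted over the list alone (camera adjusted p = 7.92e-05, adjusted p = 0.0856 with an estimated correlation). It was the matrix gene Sparc (1.48, SE 0.34), kept in 1 of 6 such fits (up to 0.159 without knockout replicate 1), and Col1a1 (2.21, SE 0.69) and Postn (2.67, SE 0.91) were not called by edgeR. DESeq2 called both, and edgeR without a filter on low values called Col1a1. Of 16 endothelial markers none was called by edgeR in either count, and DESeq2 called Pecam1 (camera adjusted p = 0.0106, adjusted p = 0.0874 with an estimated correlation), with Pecam1 at 1.21 (SE 0.42), Cdh5 at 2.01 (SE 0.86) and Kdr at 0.70 (SE 0.30). Of 14 alpha-cell markers 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 0.0689, and 0.0269 without wild-type replicate 1).

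Of 7 PP-cell markers 1 rose (camera adjusted p = 0.197), of 14 ductal markers 1 rose and 1 fell (0.268), and of 17 acinar markers none was called (0.788), with the same counts when adjusted over each list alone. Gcg, the glucagon gene of alpha cells, chosen after its values were seen, rose by 0.17 (SE 0.03), from 25264 ± 199 to 28487 ± 1226 CPM, and exceeded Ins2 in the sorted cells of both genotypes. Its call was lost without a filter on low values (adjusted p = 0.0878, the highest over its alternatives).

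**Figure D4:**
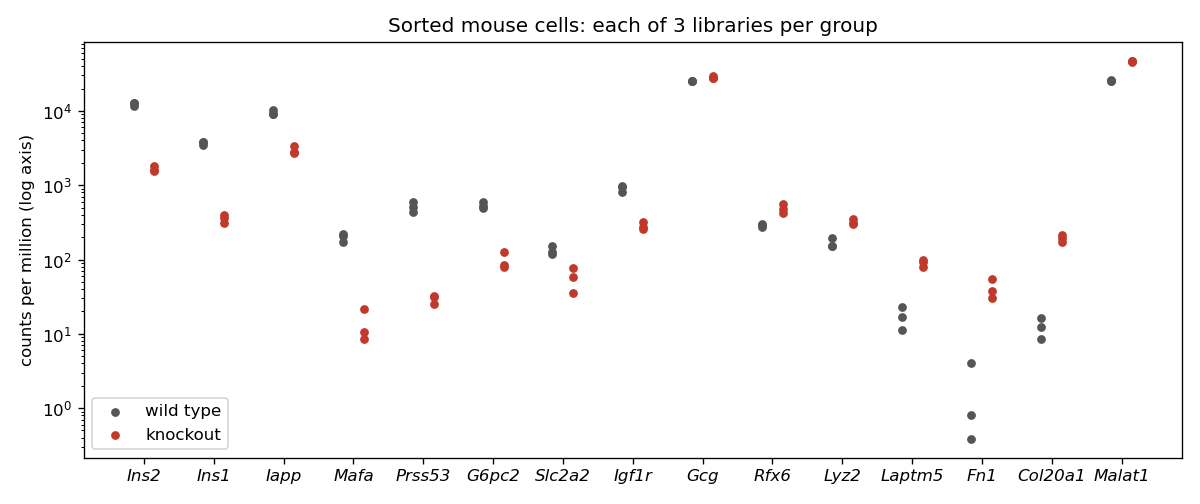
CPM on a log axis of selected beta-cell genes, markers of other cell types and other genes in sorted mouse beta cells. Each point is 1 library, in grey for wild type and red for knockout (n = 3 each).

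The protein synthesis and energy lists were lower in the knockout too, beside the higher immune, stellate and endothelial marker lists given above. In the same libraries the nuclear RNA Malat1 made up 2.54% of counts in wild type and 4.65% in the knockout, and the ribosomal RNA precursor Rn45s 4.05% and 4.84%, both chosen after their values were seen. Of 75 ribosomal protein genes 4 fell and none rose, and 5 fell when adjusted over the list alone (median log2 fold change -0.61, camera adjusted p = 2.54e-10, adjusted p = 0.0825 with an estimated correlation). Rps6 (-1.44, SE 0.28), Rpl13a (-0.66, SE 0.13) and Rpl4 (-0.60, SE 0.13) fell, with calls kept in 3, 2 and 1 of 6 fits with a library left out (adjusted p of up to 0.0655 and 0.0782 without wild-type replicate 2 and 0.108 without wild-type replicate 3). Of 74 OXPHOS genes 2 fell and none rose, and 1 rose and 8 fell when adjusted over the list alone (median -0.81, camera adjusted p = 5.55e-10, adjusted p = 0.0825 with an estimated correlation). Atp5a1 (-0.61, SE 0.13) and Ndufc1 (-3.57, SE 0.85) fell, with calls kept in 2 and 1 of 6 such fits (up to 0.113 without wild-type replicate 3 and 0.196 without wild-type replicate 1), and Ndufb9 had -1.81 (SE 0.47, adjusted p = 0.0574), called by DESeq2 and by edgeR without a filter on low values. Of 21 glycolysis genes 1 fell, and 2 when adjusted over the list alone (median -0.28, camera adjusted p = 0.0386, adjusted p = 0.304 with an estimated correlation). Aldoa fell by 0.64 (SE 0.13), not called without wild-type replicate 2 (0.0735) or knockout replicate 3 (0.0700), and Eno2 (-1.19, SE 0.33) and Pfkl (-0.84, SE 0.29) were not called by edgeR. DESeq2 called both, and edgeR without a filter on low values called Eno2. The glycolysis list was not called without wild-type replicate 1 (0.153) or 2 (0.137), or without knockout replicate 1 (0.0872) or 2 (0.0571).

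Cholesterol synthesis and proteasome genes had lower medians without any member called by edgeR in either count, whereas DESeq2 and edgeR without a filter on low values called Psmd1. The lists of this paragraph moved in the same libraries in which Malat1 and the immune, stellate and endothelial marker lists were higher. For 25 cholesterol genes the median log2 fold change was -0.38 (camera adjusted p = 0.00572, adjusted p = 0.0828 with an estimated correlation), with Insig1 at -0.50 (SE 0.21). For 37 proteasome genes it was -0.38 (camera adjusted p = 0.0129, adjusted p = 0.0856 with an estimated correlation), with Psmd1 at -0.74 (SE 0.21), Psmb6 at -0.73 (SE 0.33) and Psmc3 at -0.79 (SE 0.43). Of 28 genes of the unfolded protein response 2 rose and 4 fell, and 2 rose and 6 fell when adjusted over the list alone (median -0.25, camera adjusted p = 0.0106, adjusted p = 0.12 with an estimated correlation). The stress regulator Atf4 fell by 0.84 (SE 0.15), Pdia4 rose by 0.87 (SE 0.16) and Hyou1 fell by 0.58 (SE 0.13), the last kept in 1 of 6 fits with a library left out (adjusted p of up to 0.149 without wild-type replicate 3). Of 25 immediate early genes 3 rose and none fell, and 5 rose when adjusted over the list alone (median 0.40, camera adjusted p = 0.00403, adjusted p = 0.0825 with an estimated correlation). Btg2 rose by 0.98 (SE 0.12), Nr4a1 by 1.06 (SE 0.23) and Jun by 0.57 (SE 0.13), the last pair kept in 1 and 2 of 6 such fits (up to 0.104 without knockout replicate 1 and 0.123 without knockout replicate 3).

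Knockdown and knockout were compared over genes of the same symbol to ask whether the human line and the mouse cells changed alike. TLE3 fell and RFX6 rose in all 3 comparisons, and both were chosen after their values were seen in the mouse. The other genes called in all 3 were KLHL24 and CXXC4, higher in each, and HADH, EEF1A1 and HSPA8, lower in each. In contrast, DSP, HN1L, MAP1B and USO1 were higher in both knockdowns and lower in the knockout. Mouse Tle3 had a log2 fold change of -1.07 (SE 0.21, adjusted p = 0.0108) and Rfx6 of 0.75 (SE 0.14). Tle3 was not called without wild-type replicate 3 (adjusted p = 0.0951), knockout replicate 2 (0.0667) or knockout replicate 3 (0.0665), and Rfx6 without wild-type replicate 2 (0.0621) or knockout replicate 1 (0.0569). The Spearman correlation of the METTL14 knockdown with the knockout was 0.075 over 9866 genes, and that of the METTL3 knockdown 0.027 over 9826 genes. With the METTL14 knockdown, 7 genes rose in both (2.57 for independent lists), 10 fell in both (2.90), 14 rose in the knockdown and fell in the knockout (4.73), and 1 fell in the knockdown and rose in the knockout (1.57). With the METTL3 knockdown these counts were 8 (2.60), 9 (5.10), 10 (4.82) and 9 (2.75).

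The m6A peaks were compared to ask where IP changed relative to input. The METTL3 list held 10591 peaks in 3352 genes and the METTL14 list 11547 peaks in 3531 genes. Of the 10362 and 11277 peaks placed inside their gene, 41.9% and 42.9% lay in the last 10% of the gene span. A peak in CSTF2T, which encodes a cleavage stimulation factor, was called lower after siMETTL3 (chromosome 10, 51698062 to 51698110, minus strand, hg38, log2 change of IP over input -7.01, SE 0.89, adjusted p = 0.00441). Its IP counts were 157, 285 and 298 in the controls and 251, 236 and 311 after siMETTL3, and its input counts were 0, 1 and 0 against 43, 56 and 67. A peak in PRKACA, which encodes a catalytic subunit of protein kinase A, was called lower after siMETTL14 (chromosome 19, 14117551 to 14117648, minus strand, -4.23, SE 0.50, adjusted p = 0.00149). Its IP counts were 1947, 928 and 748 against 1666, 1426 and 803, and its input counts were 22, 12 and 31 against 446, 398 and 462. Input counts were higher at both peaks after knockdown, and the IP counts alone had log2 changes of 0.20 (SE 0.25, adjusted p = 0.710) and 0.11 (SE 0.31, adjusted p = 0.888). Neither peak was called with the input value of the gene in place of that of the peak (log2 change -0.0042 and 0.038), an alternative chosen after seeing the data. The CSTF2T call was lost without siControl replicate 2 (adjusted p = 0.0643), siControl replicate 3 (0.160), siMETTL3 replicate 1 (0.0578) or siMETTL3 replicate 2 (0.0530).

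Peaks of the fixed beta-cell genes were not called by the interaction test, whereas IP counts alone called AKT1 after siMETTL3 (-0.83, adjusted p = 0.0307) and NKX6-1 after siMETTL3 (-1.40, adjusted p = 0.000149) and siMETTL14 (-1.12, adjusted p = 0.0235). In the METTL3 and the METTL14 knockdown the log2 change of IP over input was 0.06 (SE 0.16) and -0.10 (SE 0.17) at PDX1, 0.31 (SE 0.27) and 0.07 (SE 0.25) at INS, and -0.00 (SE 0.18) and -0.34 (SE 0.18) at MAFA. At AKT1 it was -1.06 (SE 0.39, adjusted p = 0.545) and -0.80 (SE 0.38, adjusted p = 0.633). At NKX6-1 it was 0.62 (SE 0.32) and -0.07 (SE 0.29), at IGF1R -0.51 (SE 1.17) and 0.34 (SE 0.64), and at IRS2 1.04 (SE 0.86) and 1.90 (SE 0.85). The IGF1R peaks of the METTL3 and the METTL14 list did not overlap, and the INS, MAFA and AKT1 peaks had different bounds. The values of these genes therefore do not compare the knockdowns at the same site. In all, 10562 and 11490 peaks were tested by edgeR, with 1 called in each knockdown and 720 and 908 with an unadjusted p under 0.05. By limma on the difference of log2 IP and log2 input 0 and 0 were called, with 653 and 824 unadjusted. At an FDR under 0.05 the authors' tables listed 891 peaks for METTL3 (510 lower, 381 higher) and 745 for METTL14 (444 lower, 301 higher), of which 1 and 1 were called here. The authors' log2 ratio of the AKT1 peak was -1.15 (FDR 0.00168) after siMETTL3.

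Over the 5115 peaks at the same position in both lists, the METTL14 and the METTL3 knockdown were tested against each other. The interaction test called 0 of 5114 peaks (smallest adjusted p = 0.229, 299 unadjusted), and the test on IP counts alone called 102, 68 higher and 34 lower in the METTL14 knockdown.

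**Figure D5:**
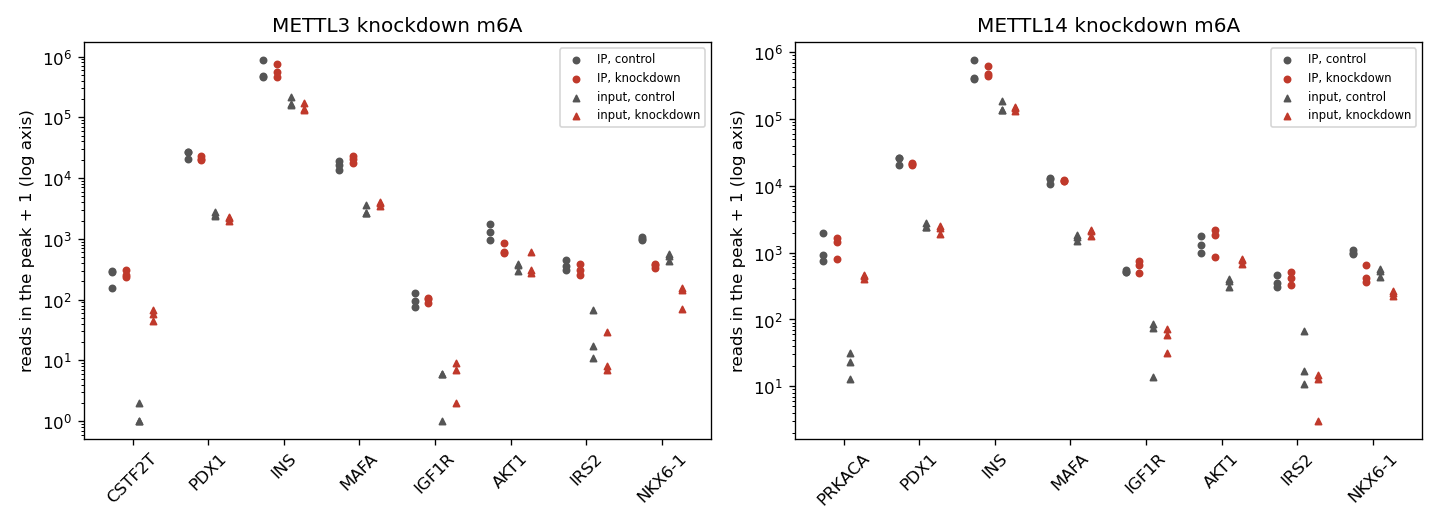
Reads plus 1 on a log axis at the called peak and the fixed-gene peaks in the METTL3 (left) and the METTL14 knockdown (right). Circles are IP and triangles input libraries, in grey for controls and red for knockdowns (n = 3 each).

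Genes with a listed peak had lower log2 fold changes than genes without. In the METTL3 knockdown the median was -0.08 for 3311 genes with a peak and 0.06 for the others (camera p = 0.000422, p = 0.281 with an estimated correlation). In the METTL14 knockdown it was -0.09 for 3488 genes and 0.06 (camera p = 8.89e-06, p = 0.0829 with an estimated correlation). In the mouse knockout, with the human peaks taken by symbol, it was -0.12 for 3098 genes and 0.07 (camera p = 0.00336, p = 0.00464 with an estimated correlation). Peaks are found more readily in transcripts with more reads. Among genes above the median expression the camera p with the preset correlation was 0.000155, 2.46e-05 and 0.00932. These held 3213, 3371 and 2174 of the genes with a peak, and expression was not matched within them. This split therefore cannot tell an effect of expression level from that of a peak. The genes with a called peak, CSTF2T and PRKACA, had expression log2 fold changes of 0.25 (SE 0.16) and 0.09 (SE 0.10) and were not called.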

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

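Among the tests below, those of a lower share of beta cells, of input counts at the peak, and of IP counts between both knockdowns were chosen after the result was seen. Groups held 3 samples, so no screening for single samples far from their group was made.

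For UQCRFS1, PPP1R1A, SEMA4G and G6PC2 the groups lay apart without overlap in opposite directions in the METTL14 knockdown of human cells and the Mettl14 knockout of mouse cells. These differences between systems were not tested, and of these genes PPP1R1A alone was called in both. They are not the only such genes. Among 9866 genes of the same symbol, 14 were called higher in the METTL14 knockdown and lower in the knockout, and 1 the reverse. In the same comparison 7 were called higher in both and 10 lower in both. UQCRFS1 had a log2 fold change of -0.66 (SE 0.14, adjusted p = 0.00584) in the knockdown and 0.83 (SE 0.25, adjusted p = 0.117) in the knockout. PPP1R1A, an inhibitor of protein phosphatase 1, had 0.72 (SE 0.18, adjusted p = 0.0223) and -2.05 (SE 0.49, adjusted p = 0.0394). SEMA4G had -0.43 (SE 0.22, adjusted p = 0.297) and 2.71 (SE 0.56, adjusted p = 0.0164), and G6PC2 had 0.34 (SE 0.19, adjusted p = 0.340) and -2.46 (SE 0.19, adjusted p = 1.55e-06). The UQCRFS1 call in the knockdown was lost without siControl replicate 1 (adjusted p = 0.0569). The PPP1R1A call there was lost without siControl replicate 1 (adjusted p = 0.128), siMETTL14 replicate 1 (0.0770) or siMETTL14 replicate 2 (0.0825). The Sema4g call was kept in 2 of 6 fits with a library left out, with an adjusted p of up to 0.0843. In the METTL3 knockdown G6PC2 was called higher (0.93, SE 0.19, adjusted p = 0.00314), against -2.46 in the knockout. MAFA was called higher there as well (0.39, SE 0.12, adjusted p = 0.0498), against -3.87 in the knockout. That MAFA call was kept in 1 of 6 fits with a library left out. Between the METTL14 and the METTL3 knockdown, 102 shared peaks differed in IP counts by a direct test, whereas 0 differed in IP relative to input (edgeR, 299 at an unadjusted p under 0.05).

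Ins1, Ins2, Iapp and Mafa were lower in the knockout while immune, stellate, endothelial and delta-cell marker lists were higher. A lower share of beta cells would raise markers of all other types alike. The median log2 fold change of stellate and fibroblast markers exceeded that of alpha-cell markers by 1.28 (two-sided permutation p = 0.00049). These lists had the highest and lowest medians among other cell types (1.48 and 0.20). They were picked after the values were seen, so this p-value cannot decide. A lower share alone would also lower transcripts made only in beta cells by the same amount. With a library left out, log2 fold changes were -3.45 to -3.28 for Ins1, -2.97 to -2.86 for Ins2 and -1.79 to -1.63 for Iapp. For Mafa they were -4.37 to -3.63. For transcripts confined to beta cells, these unequal falls, compared after they were seen, argue against a lower share as the only cause. A lower share as part of the cause stays open. Ins1, Ins2 and Iapp made up at most 2.59% of the counts, and the loss of all their counts could raise other genes by no more than 0.038 on the log2 scale, against a median of 0.88 for immune-cell markers. A change in the number of cells of the types whose markers rose stays open, and Gcg, the glucagon gene, stood at 25264 CPM in the sorted wild-type cells, above Ins2 at 12350. An effect of Mettl14 loss on beta-cell genes remains a hypothesis, and Mettl14 reads did not fall in the knockout libraries.

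Ribosomal protein genes were lower in the METTL3 knockdown, the METTL14 knockdown and the mouse knockout. Random lists matched for genomic span and expression had a median of -0.080 in the METTL3 and -0.13 in the METTL14 knockdown. The ribosomal protein medians were -0.26 and -0.37, below that of 100% of 10000 such lists in both. The random lists lack the correlation between ribosomal protein genes (estimated at 0.557 and 0.413). That share therefore cannot decide whether these features were the whole cause. With each library left out in turn the highest camera adjusted p over the 3 comparisons was 1.73e-05, which argues against a single library. With an estimated correlation the list was not called in any of them (adjusted p = 0.640, 0.333 and 0.0825), so a common shift of these genes between libraries may have contributed. The controls shared by both knockdowns stay open as a source of the shared part, and a biological effect of m6A loss was not tested apart from them.

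The authors' tables listed 510 and 444 peaks as lower after siMETTL3 and siMETTL14. Among the 484 and 430 of these that were tested and had a finite ratio, the input changed more than the IP at 93.2% and 86.5%, with a median log2 change of 1.71 and 1.72 in input and of -0.15 and -0.36 in IP. The ratio of the median change of the gene to that of the input at the peak was no higher than -0.033. Its size cannot decide, since these peaks were selected on a ratio that contains that input. The gene-level medians themselves were -0.076 and -0.057, and the gene was higher at 38.6% and 37.7% of these peaks. Medians below 0 argue against a higher transcript level at these peaks as a set. The input also changed more at 97.2% and 90.0% of the peaks they listed as higher. All these peaks were selected on a ratio that contains the input, and input counts varied more than IP counts. A larger change of input could follow from that selection alone, and its share over all tested peaks was not computed. Input counts stay open as a source of calls in both directions. Why more peaks were lower than higher was not tested. A loss of m6A after knockdown stays open, since no spike-in was described and IP counts were scaled within peaks.

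The 6 libraries of a comparison allow 10 splits into groups of 3, too few for a share under 0.05. The real split called 839 genes in the METTL3 knockdown, 586 in the METTL14 knockdown and 307 in the mouse knockout, and the highest other split called 0 in each by the same test, so that 1 split reached the real count. For peaks the real split called 1 in each knockdown and the highest other split 1, so that 2 splits reached it. With IP counts alone the real split called 605 and 181 peaks, and the highest other split 1 and 0, so that 1 split reached the real count.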

How the results depend on the processing

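The edgeR test on rounded values, other pseudocounts, the gene's input in place of the peak's, tied IP and input, the shared-peak test, and left-out libraries for lists, correlations and genes with a peak were chosen after seeing the data.

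Over all alternatives the named genes kept their side of the threshold in 1612 values, lost the call in 194 and gained it in 22. Of these genes METTL3 in the METTL14 knockdown (-0.30 to 0.28 with a library left out) and Mettl14 in the knockout (-0.33 to 0.38) changed sign, neither of them called. Lists kept their side in 522, lost the call in 31 and gained it in 7. Named peaks kept it in 195, lost the call in 7 and gained it in 2, and 4 reversed with a call on either side. Uncalled peaks also changed sign under some alternatives. The cause of the changes below was not tested unless stated.

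DESeq2 called 387 genes lower in the METTL14 knockdown, and 515 higher and 531 lower in the mouse. Without a filter on low values 210 genes were higher and 128 lower in the METTL14 knockdown, and 217 and 332 in the mouse. With an estimated correlation 0, 0 and 0 lists were called by camera in the METTL3 knockdown, METTL14 knockdown and mouse, and genes with a peak gave p = 0.281 and 0.0829 in the knockdowns. Unchanged groups simulated against shared controls gave a covariance of 0.106.

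IP counts alone called 307 peaks higher and 298 lower after siMETTL3 and 115 and 66 after siMETTL14. This test takes in changes of the transcript and also leaves out the more variable input counts. Which of these gave more calls was not tested. The test on IP counts alone reversed the sign at CSTF2T (0.20), PRKACA (0.11) and NKX6-1 (-1.40 after siMETTL3). With the gene's input value CSTF2T was at -0.0042 and PRKACA at 0.038. By limma on log2 IP minus log2 input 0 and 0 peaks were called lower (653 and 824 of either direction unadjusted), and with the gene's input value 0 and 0. Genes with a peak called lower by IP alone had median expression changes below those of other genes with peaks by -0.54 and -0.24 (two-sided permutation p = 1e-05, the smallest the permutations can give), against positive differences for the single genes of the interaction test. The IP counts of a peak also follow its transcript.

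With each library left out, the METTL3 knockdown had 134 to 975 genes higher and 148 to 950 lower, the METTL14 knockdown 112 to 371 and 62 to 199, and the mouse 56 to 82 and 72 to 114. Peaks after siMETTL3 numbered 0 to 1 higher and 0 to 1 lower, and after siMETTL14 1 lower each time. Lists called numbered 2 to 4, 4 to 6 and 12 to 13.

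Equally numbered knockdown and control libraries deviated from their group means with correlations across genes of -0.33 to 0.04, so the numbers did not pair them. With the replicate number as a block, 725, 459 and 349 genes and 2, 5 and 13 lists were called. The block changed the call of MAFA (adjusted p = 0.116) and METTL14 (0.0469) in the METTL3 knockdown, of the cell-cycle list in the METTL14 knockdown (0.0685), and of Eno2 (0.0433) and Ndufb9 (0.0461) in the mouse, and of no other named gene, list or peak. With IP and input of the same number tied as a block within a sample, 1 peak was called in each knockdown and 474 and 660 had an unadjusted p under 0.05, against 720 and 908 without it and 528 and 574 by chance. The direct expression test of both knockdowns and its block were not run, since control values differed between the tables. Input counts were lower and more variable than IP counts, with a median of 44 and 42 reads per peak against 142 and 136 for IP and a biological coefficient of variation of 0.610 and 0.612 against 0.161 and 0.196.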

Other observations

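The genes below were chosen after their values were seen, and no explanation was tested. In the METTL14 knockdown the m6A reader genes YTHDC2 and YTHDC1 rose, by 1.13 and 0.56 on the log2 scale. Of 11 m6A erasers and readers there, 2 were called higher and 0 lower, and 4 had negative changes. That list was not called (camera adjusted p = 0.474), and in the METTL3 knockdown 0 of 11 members were called. In the METTL3 knockdown 6 of 13 alpha-cell markers fell and 3 rose (4 rose and 6 fell when adjusted over the list alone), with TTR at -0.87 (SE 0.13), TM4SF4 at -1.93 and a camera adjusted p of 0.254. PGK1, a glycolysis gene, fell by 0.87 (SE 0.15) in the same knockdown. In the mouse, Malat1, a nuclear non-coding RNA, rose from 25735 ± 478 to 46089 ± 498 CPM (SD, n = 3, log2 fold change 0.84, SE 0.02). Human MALAT1 rose as well in the METTL14 knockdown (log2 fold change 0.50, SE 0.11), but was not among the genes called in both knockdowns.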
